A study of Drosophila melanogaster with 8 samples.

How the data were processed

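Ovaries of Oregon-R wild-type flies and of flies with the egt17 or egt8 null allele were profiled by total RNA and small RNA sequencing, with 4 libraries for each assay: 2 wild type, 1 egt17 and 1 egt8. Per the labels' protocols, flies were kept at a constant temperature, ovaries were dissected in cold buffer, RNA was isolated with a phenol reagent, and a sequencing company made the libraries. Per the submitters' processing notes, Bowtie2 2.2.4 and the dm6 build were used, with no role given; the counting tool, the treatment of reads that map to several places and the use of strand are not given in the sources used here.

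For total RNA the authors deposited FPKM with 1 added, for 35502 rows; the lowest value of every library was exactly 1, so 1 was subtracted to give FPKM. Of these rows, 35327 were transcripts, 32952 of which matched a gene of the reference annotation, and 175 were transposons, 52 of them from other species. The ratio between transcripts of a gene was not constant in any of 5677 pairs checked, with a median log2 range of 0.286. Transcripts of a gene were summed, which gave 18984 genes and transposons. Transcripts that share only part of their sequence would also fail that check if shared reads were counted for each. It thus cannot show that reads were apportioned, and a sum may count shared reads more than once. For small RNA the authors deposited a value for each of 94 clusters, taken as RPKM because each value times the cluster length was a whole multiple of 1 step in each library (94 of 94 values in every library, with a tolerance of 0.01). Read depth was estimated from those steps, and in total RNA only 29.8% to 38.2% of the checked low values came out whole at the same tolerance, so those depths are approximate. Cluster read numbers are recovered from the same steps, and shares carry 95% exact Clopper-Pearson intervals for counting error only.

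Genes were kept with an FPKM of at least 1 in at least 2 libraries (8780), and clusters with a mean of at least 1 RPKM (92). Differences between null and wild type were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), two-sided, with a mean-variance trend for genes and none for clusters, and Benjamini-Hochberg adjustment at 0.05. No further scaling was applied. The 2 alleles were taken as replicates of the null genotype, leaving 2 residual degrees of freedom. For clusters the fit gave every cluster the same spread. Fold differences are on the log2(value + 1) scale, with SE from the fit. Of 24 gene lists fixed before the data were examined, 18 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, with fry beside it. None of the 5 lists that passed at the preset correlation passed with the estimated correlation, and fry gave adjusted p of 0.757 or more for every list. With an estimated correlation camera rests on the 2 residual degrees of freedom, which by itself limits it. For somatic transposons the estimated correlation was -0.062, under the preset 0.01, yet the camera p rose from 3.28e-05 to 0.0514. Over all alternatives the lowest adjusted p was 0.470 with the estimated correlation and 0.371 with fry. The histone H1 entry of the nuclear silencing list matched a single copy of a multicopy gene and is uncertain. A Fisher exact test and a permutation test with 100000 resamples were used in the closing section. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

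Library pairs (wild type 1 with egt17, wild type 2 with egt8) were recognised from depth and from the correlation of total RNA after the data were examined, and the same pairs were used for small RNA. Deviations from the group means correlated at 0.763 between wild type 1 and egt17; with 2 libraries in each group this is the only independent value. The fits with the pair as a term, with 1 residual degree of freedom, were added then, as were the count over every listed transposon as 1 list, the within-pair medians of genes overlapping clusters, and the simulation of unchanged mutants with the pair difference kept. The other tests of the comparisons and their alternatives were fixed before. The tests of explanations in the closing section were chosen after the results were seen, except the comparison with other splits of the libraries.

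Named genes followed a rule fixed before the data were examined: the mutated gene (taken to be Boot) first, then up to 12 genes in each direction past the threshold, filled up to 6 by size where fewer passed, among genes at least 2-fold apart in both alleles with a mean FPKM of at least 5 in the higher group, given as values; any list member could also be named. The 13 genes and transposons past the threshold with the pair term were named after their values were seen. For clusters the rule took the 42AB, 38C, 80F, flam and 20A regions and the 5 largest falls and 5 largest rises with a mean of at least 23.1 RPKM, the upper quartile, since only 5 clusters reached 100 RPKM.

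The fits were tested on simulated data over the 8780 genes, with 200 genes changed in each of 20 simulations. With the pair difference as measured and no pair term, 0% of genes changed 2-fold, 4-fold or 16-fold were recovered. With the term, 35.2%, 89.3% and 99.7% were recovered and 8.41% of calls were false when variances were drawn from the fitted prior, and 82.7%, 99.6% and 100% with 18.2% false when each gene had its moderated variance. With no pair difference and no term, 90.3% of genes changed 4-fold were recovered and 5.07% of calls were false with variances from the prior. For clusters 379 of 400 changed 4-fold were recovered, with 15 false calls among 1440 unchanged, in data simulated without a pair difference. A list of 20 genes changed 4-fold was recovered by camera at the preset correlation in 20 of 20 simulations. Those genes were drawn at random, with noise independent between genes. The estimated correlation was 0.62 for chorion genes and 0.68 for muscle genes. The simulation thus does not test camera for lists whose members move together.

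Alternatives covered the pseudocount, the filter, quantile and median-ratio scaling, the variance trend, the transcript rule, a minimum fold of 1.5, cluster scalings, and leaving out each library. Tools for counts were not run, since the values are not counts. Reads of transposon families and of repeat-rich clusters may be shared between copies, so a family or cluster value is not that of a single locus.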

Results

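The series measured RNA and small RNA in dissected ovaries of Drosophila melanogaster, from Oregon-R wild-type flies and from flies carrying either of 2 alleles, egt17 and egt8, that the labels describe as null. Oregon-R is a common laboratory wild-type strain, and the series names the mutated gene boot. Total RNA and small RNA were each sequenced in 4 libraries, 2 from wild type and 1 from each allele, and the alleles served as the 2 replicates of the null genotype. The values stepped by whole reads in part, which gave an estimated depth of 6.32 M reads for wild type 1, 16.6 M for wild type 2, 6.15 M for egt17 and 15.9 M for egt8 in total RNA. In small RNA the same reading gave 19.6, 6.78, 22.9 and 5.99 M reads in that order. The labels do not say that the libraries came from separate groups of animals. Limma p-values here thus measure only the spread between these libraries, which may be technical. Camera at its preset correlation, and the Fisher test and gene permutation of the closing section, compare genes with other genes. Genes are not independent replicates.

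The total RNA libraries resembled each other by pair rather than by genotype. Across 8780 genes and transposons, log2 values correlated at 0.966 between wild type 1 and egt17 and at 0.948 between wild type 2 and egt8. The correlation was 0.901 between the wild-type libraries and 0.876 between the mutant libraries. These are correlations across genes, which are not independent replicates. Depth followed the same pairs, each of which held 1 wild-type and 1 mutant library. In small RNA depth did so too, but log2 values of clusters correlated more within genotypes (0.954 for wild type, 0.922 for the mutants) than within the pairs (0.785 and 0.841). The labels name no batch, so medians within each pair are given beside the pooled ones for lists that passed a set test with all libraries and the filter or that went opposite ways in the pairs.

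The first check was of Boot. The series names boot and the labels name the alleles egt, and that both mean the gene Boot was assumed here. Boot, also known as Bootlegger, is a germline protein that acts with the export receptor Nxf3 on piRNA cluster transcripts, and piRNAs are small RNAs that silence transposons. The gene (FBgn0033374) lies on chromosome 2R from 9092506 to 9094658 in the reference annotation. Its RNA stood at 88.6 and 89.7 FPKM in wild type 1 and wild type 2, against 40.6 FPKM in egt17 and 52.1 FPKM in egt8. The log2 difference was -0.94 ± 0.32 (SE, n = 2 against 2), lower in both alleles, with a limma adjusted p of 0.9999. With a term for the library pair the limma adjusted p was 0.169. Boot RNA was lower in each mutant library than in each wild-type library, and the difference did not pass the test over all genes.

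Transposon transcripts were more abundant in the mutant libraries. Of 121 listed transposons of the studied species, 43 passed the filter and were tested. Of these 43, 41 had a positive log2 difference. At least 2-fold higher in both alleles than in both wild types were 20, with 0 at least 2-fold lower. An element under 1 FPKM in both wild types, such as Burdock, could pass the filter only by being higher in both mutants. Likewise Bari1, under 1 FPKM in both mutants, could pass only by being lower. The counts thus do not give the share of all listed elements that changed. Burdock, a long terminal repeat element, stood at 0.271 and 0.742 FPKM in wild type and at 79.98 FPKM in egt17 and 165 FPKM in egt8, a log2 difference of 6.28 ± 0.54. HeT-A, the retrotransposon that maintains fly telomeres, went from 0.858 and 1.30 FPKM to 75.7 FPKM in egt17 and 174 FPKM in egt8, a log2 difference of 5.81 ± 0.55. Differences were of similar size for Transpac (6.07 ± 0.82) and blood (5.83 ± 0.47), and smaller for 3S18 (4.53 ± 0.73) and HMS-Beagle (4.48 ± 0.54). These differences are on the log2(FPKM + 1) scale, which understates the change of elements near 0 in wild type.

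Of the 23 tested members of the list of germline transposons, 22 were higher, with a median log2 difference of 2.08. The filter can be met through the mutant libraries alone, and the median moved with it: 0.87 with no filter (35 members, 31 higher and 4 lower) and 4.38 at an FPKM of at least 5 (13 members, all higher). By limma, 0 of the 23 passed when adjusted over all genes and 9 passed when adjusted over the list alone. With no filter 6 of the 35 members passed adjusted over the list alone. With the library pair as a term, chosen after seeing the data, 6 passed over all genes and 15 adjusted over the list alone. The camera set test with its preset correlation gave an adjusted p of 2.91e-32, and an adjusted p of 0.508 with an estimated correlation. The median was 1.52 in egt17 against wild type 1 and 2.06 in egt8 against wild type 2, and without egt8 the pooled median was 1.17. The I-element, at 1.24 and 1.75 FPKM in wild type, was at 4.603 FPKM in egt17 and 18.7 FPKM in egt8. Doc, with a log2 difference of 0.07 ± 0.69, and roo, with 0.22 ± 0.59, lay within their SE of 0. Copia was higher in egt17 by 1.52 and lower in egt8 by -1.13 against the paired wild types. Tirant (5.74 FPKM in egt17, 71.5 FPKM in egt8) and mdg3 (31.3 FPKM in egt17, 5.85 FPKM in egt8) had unequal values in the alleles, which was not tested.

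The list of somatic transposons, elements known for activity in follicle cells, had 5 tested members, and all 5 had a positive pooled difference, with a median of 1.12, from 0.90 in egt17 and 2.09 in egt8 against the paired wild types. The camera adjusted p was 0.000197 with the preset correlation, and the adjusted p was 0.508 with an estimated correlation. That correlation was -0.062, so the loss did not come from correlation between the members. None of the 5 passed limma over all genes or adjusted over the list alone; with the pair term 3 passed adjusted over the list alone, ZAM and accord among them, as did ZAM and accord without egt17 and accord without the variance trend. ZAM was at 0.188 and 0.285 FPKM in wild type, 1.08 FPKM in egt17 and 4.49 FPKM in egt8. Springer went opposite ways in the alleles, by -1.58 in egt17 and 2.39 in egt8. Quasimodo did so the other way round, by 0.90 in egt17 and -0.66 in egt8. Without egt8 the list median was 0.75 and the camera adjusted p was 0.0894; without egt17 the median was 1.85, and without wild type 2 it was 0.70. With no filter the list had 17 members, 15 higher and 2 lower, with a median of 0.42 and a camera adjusted p of 2.52e-05.

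**Figure D1:**
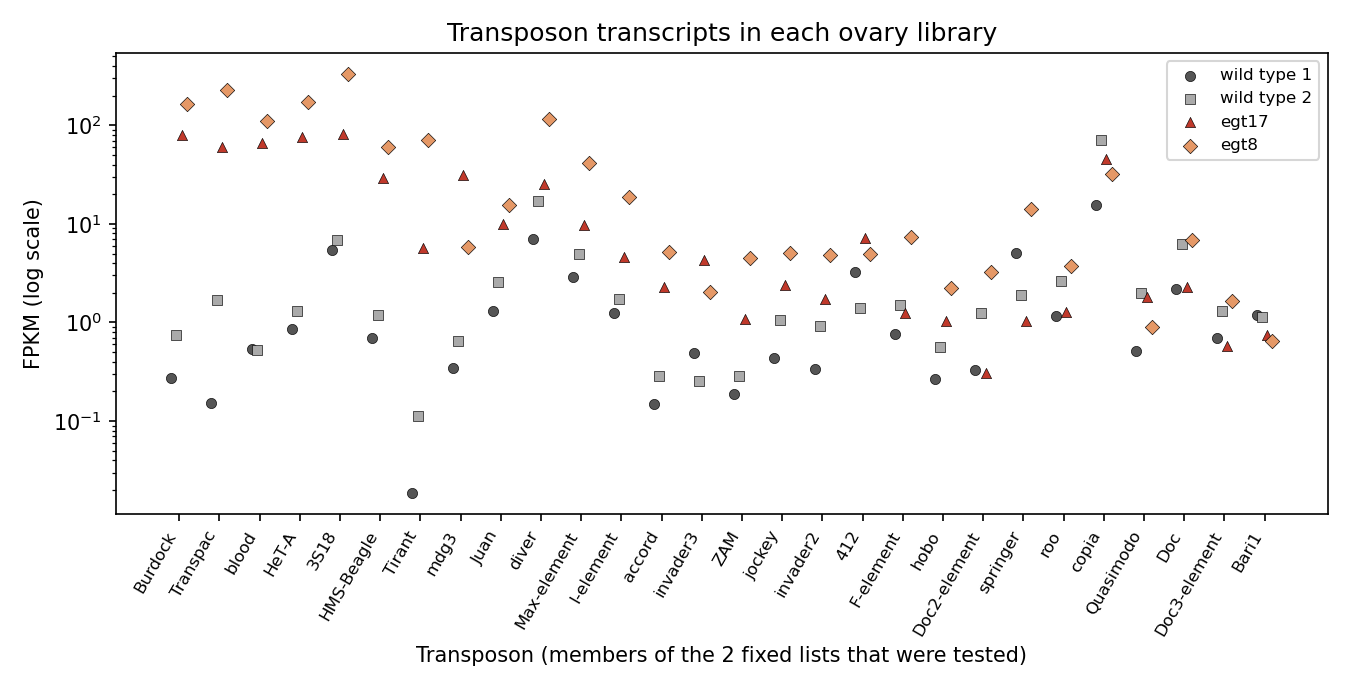
FPKM on a log scale for each tested transposon of the germline and somatic lists, ordered by log2 difference, with 1 point for each of the 4 total RNA libraries. Burdock lies at 0.271 and 0.742 FPKM in the wild-type libraries and at 79.98 and 165 FPKM in the mutant libraries, while the points of Doc and roo overlap between genotypes.

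Over all 8780 genes and transposons, limma called 0 at an adjusted p of 0.05, and 166 had an unadjusted p under 0.05, 102 higher and 64 lower in the mutants. The difference between the library pairs entered the spread of this fit. In data simulated with that pair difference the same fit recovered 0% of genes changed 16-fold. A fit with the library pair as a term, chosen after seeing the data, called 13, of which 9 rose and 4 fell. In the simulations that fit recovered 99.7% of genes changed 16-fold, and 8.41% of its calls were false. The false share was 18.2% when each gene kept its own moderated variance, and both shares are above the nominal rate. Each simulation held 200 changed genes and gave on average 13.7 or 41.9 false calls in these 2 settings. Neither the share nor the number need carry over to a fit with 13 calls, so the false share among the 13 is not known. Leaving out a library also gave calls without the term. Such a fit leaves a lone sample in a group. Its prior degrees of freedom, the weight on the spread pooled over genes, rose from 2.95 to 14.3 or more. Those calls thus lean on the pooled spread and are not added evidence.

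By size of the log2 difference, the 13 called with the pair term were led by 6 transposons. These were Burdock, Transpac, blood, HeT-A, HMS-Beagle and 3S18, with limma adjusted p from 0.00353 to 0.0307. Among genes, Arc1, which encodes a capsid-forming protein related to retrotransposon Gag, rose from 37.4 and 19.0 FPKM to 257 FPKM in egt17 and 238 FPKM in egt8 (limma adjusted p = 0.0169 with the term). CG30345, on 2R from 9148689 to 9151892 and so 56.7 kb from Boot, rose by 3.22 ± 0.24 on the log2 scale. Naglu, a lysosomal enzyme gene, rose by 1.92 ± 0.15. The 4 that fell were CG43867, Lime, CG31661 and CG4570. CG43867 (X, 808217 to 927975) fell from 17.5 and 37.8 FPKM to 1.05 FPKM in egt17 and 4.15 FPKM in egt8. Lime (2R, 9871470 to 9873646), known from hemocytes, fell from 52.5 and 72.6 FPKM to 5.08 FPKM in egt17 and 12.6 FPKM in egt8. CG31661 fell by 2.24 and CG4570 by 1.60 on the log2 scale. CG4570 was at 370 and 126 FPKM in wild type, 124 FPKM in egt17 and 40.3 FPKM in egt8, and its log2 difference was -0.82 without wild type 1, -2.37 without wild type 2, -2.40 without egt17 and -0.80 without egt8. The errors in this paragraph are SE from the fit with the term.

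By size alone, 115 genes were at least 2-fold higher and 58 at least 2-fold lower in both alleles than in both wild types, given as values and not as calls. That makes 173 genes, where parting the same libraries by pair set apart 1414 and parting them across the pairs set apart 55. The largest such falls outside the genes above were in CG6508 (43.1 and 21.65 FPKM in wild type, 1.53 in egt17, 7.10 in egt8), Culd (10.8 and 11.9 FPKM in wild type, 0.968 in egt17, 1.10 in egt8), CG31928 with a log2 difference of -2.37 ± 0.45 and the noncoding RNA lncRNA:CR45756 with -2.36 ± 0.47.

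Chorion genes, which encode the outer eggshell made by late follicle cells, were lower in the mutants. All 16 tested members had a negative log2 difference, with a median of -1.41, and 14 of them were lower in both alleles than in the paired wild type. Cp15 stood at 10998 and 5867 FPKM in wild type, 1148 FPKM in egt17 and 2341 FPKM in egt8. Cp18 was at 3751 and 1917 FPKM in wild type, 222 FPKM in egt17 and 1292 FPKM in egt8, and Cp19 and Cp7Fa had log2 differences of -1.89 ± 0.52 and -1.43 ± 0.36. The camera adjusted p was 1.51e-14 with the preset correlation, and the adjusted p was 0.673 with an estimated correlation. Limma called 0 of the 16, over all genes or adjusted over the list alone, and 13 adjusted over the list alone with the pair term. Some were also called adjusted over the list alone when wild type 1, wild type 2 or egt8 was left out. Such fits leave a lone sample in a group and lean on the spread pooled over genes. The median was -2.20 in egt17 and -0.66 in egt8 against the paired wild types. Without egt17 the pooled median was -0.50 and the camera adjusted p was 0.0919; without egt8 the median was -2.42.

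Other egg-forming products went opposite ways in the alleles. The vitelline membrane and eggshell patterning list (17 tested) had a pooled median of -0.26 and a camera adjusted p of 0.386, from -0.84 in egt17 and 0.48 in egt8. It passed camera in opposite directions when a library was left out: the median was -1.003 without egt8 (camera adjusted p = 2.03e-10), -0.43 without wild type 1 (0.00870) and 0.64 without egt17 (0.000558). None of these passed with an estimated correlation (adjusted p of 0.749, 0.722 and 0.617). Vm26Aa was at 3939 and 4167 FPKM in wild type, 920 FPKM in egt17 and 7033 FPKM in egt8, and Vm34Ca at 654 FPKM in egt17 and 4909 FPKM in egt8. The 4 yolk protein genes and receptor were all lower in egt17 (median -0.65) and all higher in egt8 (0.78) than in the paired wild type; Yp3 went from 579 to 270 FPKM in the first pair and from 426 to 1003 FPKM in the second. The list was too short for a set test.

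Markers of somatic follicle cells (14 tested) had a median of 0.47, with 11 higher and 3 lower. The camera adjusted p was 0.00230 with the preset correlation, and the adjusted p was 0.836 with an estimated correlation; limma called 0, over all genes or adjusted over the list alone. The medians were 0.28 in egt17 and 0.49 in egt8. The transcription factor gene tj was at 14.5 and 29.4 FPKM in wild type, 21.89 FPKM in egt17 and 59.3 FPKM in egt8, and kek1 had a log2 difference of 1.01 ± 0.55. Without wild type 1 the median was 0.0094 (camera adjusted p = 0.842) and without egt8 it was 0.00025 (camera adjusted p = 0.596); without egt17 it was 0.86.

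Muscle genes (18 tested) had 17 members with a positive pooled difference, a median of 0.53 and a camera adjusted p of 0.000379; the adjusted p was 0.836 with an estimated correlation, and limma called 0, over all genes or adjusted over the list alone. The alleles went opposite ways, with a median of -0.81 in egt17 and 1.99 in egt8. Mhc was at 8.97 and 4.36 FPKM in wild type, 2.28 FPKM in egt17 and 42.9 FPKM in egt8, and Act57B at 133 and 27.0 FPKM in wild type, 27.1 FPKM in egt17 and 265 FPKM in egt8. Without wild type 2 the muscle median was -0.03, without egt8 it was -0.27, without wild type 1 it was 1.22 and without egt17 it was 1.32. The list did not pass camera without wild type 2 or egt8, or with no filter (24 members, median 0.50, camera adjusted p = 0.163). Hemocyte markers (7 tested, median 0.44, camera adjusted p = 0.0854) moved with muscle, by -0.31 in egt17 and 1.88 in egt8, and passed camera without egt17 (median 1.17, camera adjusted p = 1.71e-05), but not there with an estimated correlation (adjusted p = 0.617). The basement membrane collagens vkg and Col4a1 were at 85.0 and 108 FPKM in egt8, against 18.8 and 26.6 FPKM in wild type 2. Their pooled log2 differences, 1.13 and 1.06, stayed positive whichever library was left out. The hemocyte median did not, at -0.22 without egt8.

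**Figure D2:**
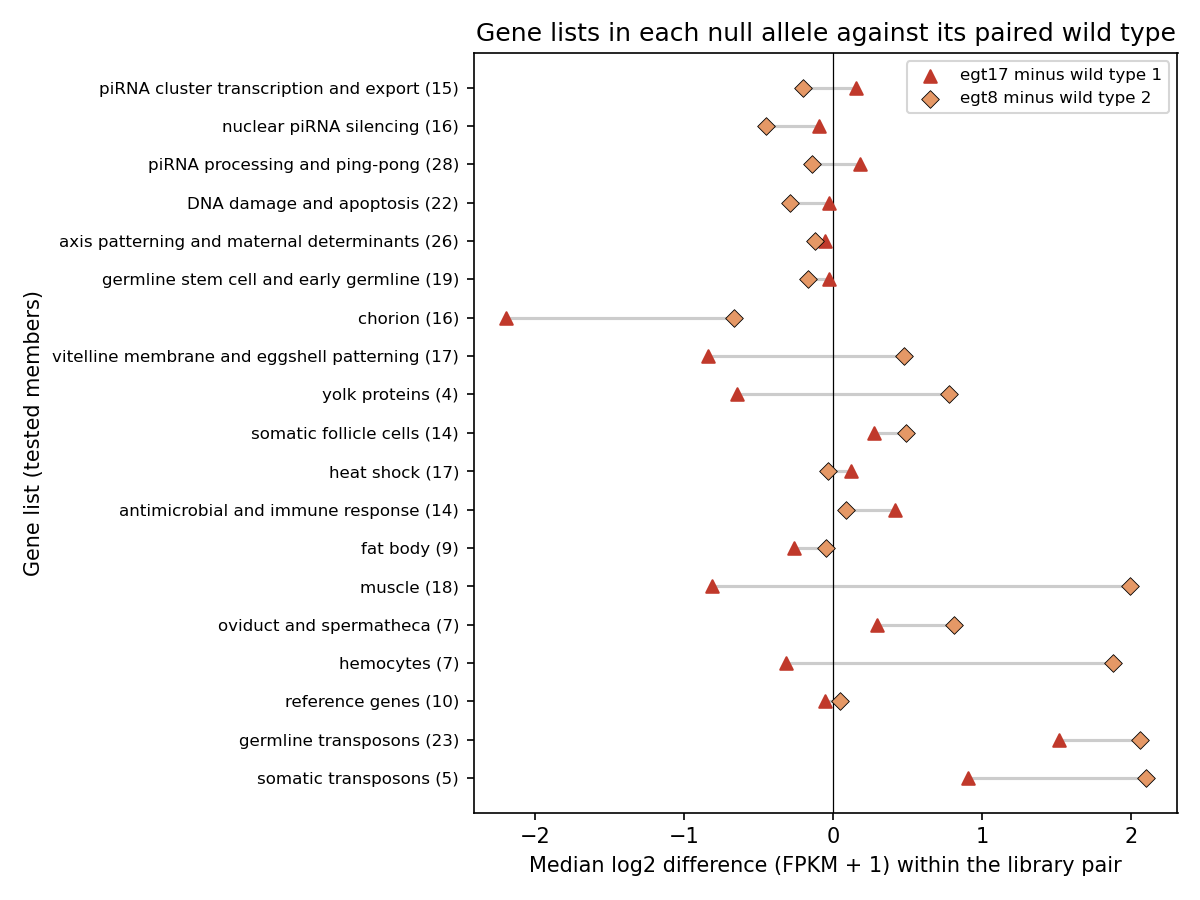
Median log2 difference of each gene list on the log2(FPKM + 1) scale, for egt17 against wild type 1 (triangles) and egt8 against wild type 2 (diamonds), with the number of tested members in brackets. Germline transposons lie to the right in both pairs (1.52 and 2.06) and chorion genes to the left in both (-2.20 and -0.66), while muscle genes lie on opposite sides (-0.81 and 1.99).

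None of the 3 lists of piRNA pathway genes passed camera with all libraries and an FPKM filter of at least 1. The list for cluster transcription and export (15 tested) had a median of 0.0068 and a mean of -0.12, with 8 higher and 7 lower and a camera adjusted p of 0.582; its median was 0.15 in egt17 and -0.20 in egt8 against the paired wild types. The cluster chromatin protein gene rhi had a log2 difference of -0.35 ± 0.41 and Nxf3 one of 0.15 ± 0.45, while moon, a transcription factor of the clusters, was at 83.9 and 41.8 FPKM in wild type, 29.5 FPKM in egt17 and 26.1 FPKM in egt8. Nuclear silencing factors (16 tested) had 14 lower members, a median of -0.23 (-0.09 in egt17, -0.45 in egt8) and a camera adjusted p of 0.0854. This list passed camera without wild type 1 (median -0.48, camera adjusted p = 0.00980), without egt8 (-0.33, 0.0448) and with no filter (0.0291); without wild type 2 its median was -0.056. With an estimated correlation it passed in none of these (adjusted p of 0.722, 0.749 and 0.829). Processing and ping-pong factors (28 tested) had a median of 0.06, from 0.18 in egt17 and -0.14 in egt8, and a camera adjusted p of 0.839; aub had a log2 difference of 0.37 ± 0.34 and vls one of -1.26 ± 0.50. Limma called 0 members of these lists, over all genes or adjusted over the list alone.

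Of the other lists, none passed camera with the preset correlation, all libraries and an FPKM filter of at least 1. With a library left out some passed as given here, and with an estimated correlation none did (adjusted p of 0.722 for each without wild type 1 and 0.749 for each without egt8). DNA damage and apoptosis genes (22 tested) had a median of -0.19 and a camera adjusted p of 0.459; lok, the fly checkpoint kinase Chk2, was at 212 and 190 FPKM in wild type, 111 FPKM in egt17 and 116 FPKM in egt8, and Xrp1 had a log2 difference of 0.87 ± 0.59. Axis patterning genes (26 tested) had a median of -0.09 and a camera adjusted p of 0.624, with exu at -0.69 ± 0.36, bcd at -0.53 ± 0.33 and nanos at -0.42 ± 0.47. Without wild type 1 the axis patterning list passed camera (median -0.39, camera adjusted p = 0.00914), as it did without egt8 (-0.28, 0.0186). Early germline genes (19 tested) had a median of -0.22 and a camera adjusted p of 0.551, and passed camera without wild type 1 (-0.51, 0.0471) or egt8 (-0.42, 0.0448). Heat shock genes (17 tested, with Hsp70 copies that share reads and so are uncertain) had a median of 0.018 (0.12 in egt17, -0.03 in egt8) and a camera adjusted p of 0.386, and passed camera without egt8 (0.46, 0.0344). Immune genes (14 tested) had a median of 0.18 and a camera adjusted p of 0.0854, and passed camera without wild type 1 (0.72, 0.00870) or egt8 (0.82, 3.54e-05). The secreted peptide gene BomS1, at 0.438 FPKM in wild type 1 and listed at 0 in wild type 2, was at 9.91 FPKM in egt17 and 3.30 FPKM in egt8. Fat body genes (9 tested) had a median of -0.03 and a camera adjusted p of 0.839, and passed camera without egt8 (-0.42, 0.0186). Oviduct and spermatheca genes (7 tested) had a median of 0.55 and a camera adjusted p of 0.394. The median was 0.19 without egt8, 0.28 without wild type 2 and 0.021 with no filter (12 members). Bbd, which was matched through a synonym, was at 1.76 ± 0.55, and its standing as a marker of these tissues is uncertain. Reference genes (10 tested) had a median of -0.06 (-0.05 in egt17, 0.05 in egt8) and a camera adjusted p of 0.959, although RpL32 was at 5661 and 6987 FPKM in the first pair and at 1131 and 1578 FPKM in the second. Without the pair term and with all libraries, limma called 0 members of these lists over all genes or adjusted over the list alone. With the pair term and adjusted over the list alone, it called lok lower, BomS1, BomS2 and BomS3 higher and Dro and Def lower among immune genes, and Bbd higher and Oamb lower in the oviduct list. Of these Def passed without wild type 2 or egt17, and BomS1 and BomS2 without egt8, with no pair term. These genes were named after their values were seen. Their log2 differences moved with the library left out, by over 1.5 times for Def (-4.65 without egt17, -0.15 without egt8), Dro (-1.89 without wild type 2, -0.26 without wild type 1), BomS3 (0.39 without wild type 2, 2.07 without wild type 1), BomS2 (0.86 without egt17, 2.88 without egt8) and Oamb (-0.71 without egt17, -1.49 without egt8). Gut (1 tested, -0.97 in egt17 and -0.58 in egt8), testis (2 tested, medians of 1.17 and 1.09) and nervous system markers (1 tested, 0.21 and -0.21) had too few members at an FPKM of at least 1 for a set test, and 0 mitochondrial genes were matched. With no filter testis (20 members, 19 higher, median 0.13, camera adjusted p = 0.000289) and gut (15 members, 12 lower, median -0.068, camera adjusted p = 0.0291) passed, nervous system markers (9 members) did not (0.412), and each had an adjusted p of 0.829 with an estimated correlation.

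Whether the alleles shared their differences was asked across genes, each allele against the mean of both wild types. The correlation was -0.02 with a covariance of -0.0095, where simulated unchanged mutants sharing those controls gave 0.33 and 0.165. That simulation left out the library pairs; with the measured pair difference kept, added after seeing the data, unchanged mutants gave -0.55 and -0.171. Against its own paired wild type, each allele's differences correlated with the other's at 0.38, and against the wild type of the other pair at -0.54. Unchanged mutants with the pair difference kept gave 0.0018 and -0.86 in these comparisons. Genes are not independent replicates, and no test was made.

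Small RNA was measured over 94 listed clusters, genomic regions that give rise to piRNAs, and 92 had a mean of at least 1 RPKM. Limma called 20 clusters at an adjusted p of 0.05, of which 15 fell and 5 rose in the mutants. An unadjusted p under 0.05 was reached by 33. The fit pooled the spread over the 92 clusters, so every cluster has the same SE of 0.44. The SE and p of a cluster thus do not rest on the spread of its own libraries, however small the p. In all, 71 of the 92 had a negative log2 difference, with a median of -0.51. The share of small RNA reads on the clusters was 13.4% and 13.5% in wild type 1 and wild type 2, 7.98% in egt17 and 11.5% in egt8. The named clusters below have no host gene unless stated, and coordinates are those of dm6.

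The largest fall was in cluster97, at the end of 2R from 25252436 to 25259156 and overlapping CG9380 and CG30428. Its small RNA went from 38.8 and 57.2 RPKM to 2.17 RPKM in egt17 and 2.86 RPKM in egt8, a log2 difference of -3.78 ± 0.44 (limma adjusted p = 3.27e-13). The cluster lies at the last annotated genes of the arm. 42AB, the best known germline cluster (2R, 6256844 to 6499214), fell from 110 and 154 RPKM to 23.23 RPKM in egt17 and 92.2 RPKM in egt8, a log2 difference of -1.47 ± 0.44 (limma adjusted p = 0.00872). Its share of the small RNA reads was 2.67% (95% exact Clopper-Pearson interval 2.67% to 2.68%) in wild type 1, 3.73% (3.71% to 3.74%) in wild type 2, 0.563% (0.560% to 0.566%) in egt17 and 2.23% (2.22% to 2.25%) in egt8; the intervals cover counting error only. Without egt17 the log2 difference of 42AB was -0.49 with a limma adjusted p of 0.540, and without wild type 1 or wild type 2 its adjusted p was 0.0985 or 0.319; without egt8 the difference was -2.44.

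Further falls passed the test in cluster66 (X, 22222591 to 22223677, -2.33 ± 0.44), cluster61 (X, 22250902 to 22259500, overlapping CG41562, -1.99 ± 0.44) and cluster56 (2R, 5367110 to 5394403, overlapping lncRNA:CR42646, -1.66 ± 0.44). At cluster27 in the 38C region (2L, 20104660 to 20118503) small RNA fell by 1.27 on the log2 scale, from 107 and 148 RPKM to 42.9 RPKM in egt17 and 62.4 RPKM in egt8. The other 38C cluster, cluster5, had a difference of -0.88 ± 0.44 that did not pass (limma adjusted p = 0.133). Its difference was -0.26 without egt17, -1.49 without egt8 and -0.33 with median-ratio scaling. None of the 6 clusters in the 80F region passed in the fit of all libraries without a pair term or further scaling. Of these cluster55, which overlaps AGO3, was higher in the mutants, with a difference of 0.44 ± 0.44. It was at 10.4 and 7.49 RPKM in wild type, 14.4 RPKM in egt17 and 10.7 RPKM in egt8. The other 80F clusters had a negative difference. Cluster5 and cluster32, the latter in 80F, passed with the pair term (limma adjusted p = 0.0490 and 0.0222), with scaling to flam and 20A (0.0467 and 0.0357) and without egt8 (0.00175 and 0.000378). Without egt8 the 80F clusters cluster6 (0.00950), cluster25 (0.0188) and cluster86 (0.0487) passed as well, the last 2 of which overlap Snap25. Cluster6, that with the highest mean, which overlaps nAChRalpha4 and alpha-Cat, was at 36.2 and 34.4 RPKM in wild type, 14.4 RPKM in egt17 and 38.5 RPKM in egt8. Without wild type 2 the calls at cluster66 and cluster61 were lost (limma adjusted p = 0.0749 and 0.151), as was that at cluster56 without wild type 1 or wild type 2 (0.215 and 0.0749) and that at cluster27 without wild type 1, wild type 2 or egt17 (0.186, 0.401 and 0.1002).

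Small RNA rose at cluster142 (2R, 5152184 to 5161219, overlapping Atf6), from 10.8 and 14.7 RPKM to 57.3 RPKM in egt17 and 85.2 RPKM in egt8. It also rose at cluster114 (X, 4128219 to 4128422, overlapping tyf, 2.35 ± 0.44) and cluster110 (X, 12770963 to 12772314, overlapping Agpat1 and CG32647, 1.45 ± 0.44). Cluster114 rested on 19 reads in wild type 2 and 61 reads in egt8; its log2 difference was 1.21 without egt17, and its call was lost without wild type 2 (limma adjusted p = 0.0955). The call at cluster110 was lost without wild type 1 (0.312) or wild type 2 (0.0955). The flam cluster (X, 21634639 to 21883809), which acts in follicle cells and overlaps lncRNA:flam, was at 96.3 and 70.6 RPKM in wild type, 125 RPKM in egt17 and 109 RPKM in egt8, a difference of 0.50 ± 0.44 that did not pass (limma adjusted p = 0.438). Its difference was 0.28 without wild type 2, 0.72 without wild type 1 and 1.08 with median-ratio scaling. Cluster2 in the 20A region (X, overlapping lncRNA:CR46472) had a difference of 0.023 ± 0.44 and cluster29 on chromosome 4, overlapping Sox102F, fd102C and CR33797, one of 0.28 ± 0.44.

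**Figure D3:**
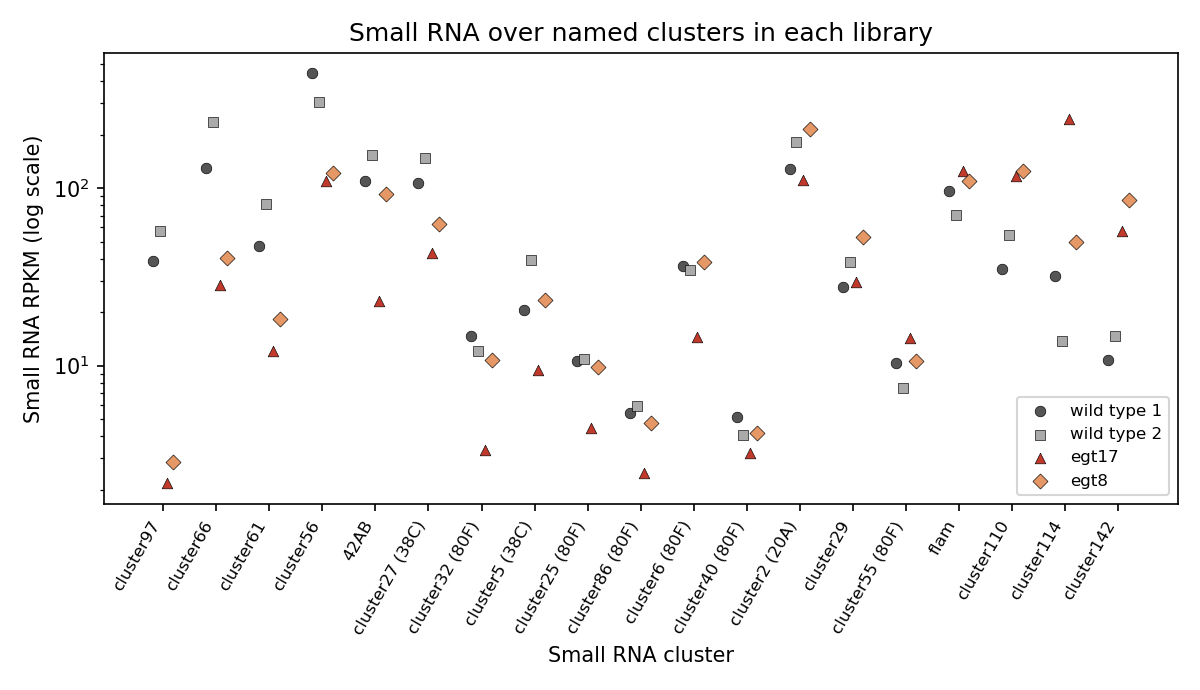
Small RNA RPKM on a log scale for each named cluster, ordered by log2 difference, with 1 point for each of the 4 small RNA libraries. Cluster97 lies at 38.8 and 57.2 RPKM in wild type and at 2.17 and 2.86 RPKM in the mutants, 42AB at 23.23 RPKM in egt17 and 92.2 RPKM in egt8, and flam is higher in both mutants (125 and 109 RPKM) than in both wild types.

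The number and the balance of called clusters moved with the scaling. Scaling by the median ratio shifted the median difference of all clusters from -0.51 to 0.0095 and left 5 calls, 4 higher and 1 lower; scaling to the cluster sum gave 13, with 6 higher and 7 lower, and scaling to flam and 20A gave 41, with 4 higher and 37 lower. Relative to the median cluster, 42AB was lower by -0.90 with a limma adjusted p of 0.276, while cluster97 (-3.29), cluster142 (2.94) and cluster110 (2.03) were the named clusters that still passed. A term for the library pair, chosen after seeing the data, gave 33 calls, 6 higher and 27 lower, including all 20. Calls numbered 6 without wild type 1, 2 without wild type 2, 12 without egt17 and 46 without egt8. Across clusters the differences of the alleles correlated at 0.825 with a covariance of 0.712, against 0.32 and 0.0997 for simulated unchanged mutants, or 0.095 and 0.0302 with the measured pair difference kept; against their own paired wild types the correlation was 0.825, and -0.0076 for those unchanged mutants.

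A ratio within each library does not depend on such scaling. For it the RPKM of clusters were summed, so a short cluster weighs as much as a long one at the same RPKM. The log2 ratio of the sum over the dual-strand clusters 42AB, 38C and 80F to that over the uni-strand clusters flam and 20A was 0.51 in wild type 1, 0.72 in wild type 2, -0.9998 in egt17 and -0.33 in egt8. The mutants were lower by -1.28 on average, with differences of -1.51 and -1.05 within the pairs. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow, so this permutation test could not pass the threshold.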

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

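The tests of explanations for muscle were chosen after the result was seen. In these lists the members' median moved up in egt8 and down in egt17 against the paired wild type, and the difference between alleles was not tested, since each allele has 1 library. These medians against the paired wild type differed between egt8 and egt17 on the log2 scale. The gap was 2.80 for muscle, 2.19 for hemocytes, 1.43 for yolk proteins and 1.32 for the vitelline membrane and eggshell patterning list.

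A different amount of muscle in the dissected tissue is a candidate explanation for the muscle pattern. Of 19 muscle markers with a mean FPKM of at least 1, 18 were higher in egt8 and 15 lower in egt17 than in the paired wild type, so the lower share was 78.9%, under the 80% set for it. The share lies between the bounds set for and against that explanation. The list was flagged because its medians went opposite ways in the alleles, so the bound against could hardly be reached. The share thus cannot decide, and the explanation stays open. A difference that both libraries of a pair share largely cancels in medians against the paired wild type, so those medians cannot test it. Wild type 2 was lower than wild type 1 (median -0.95), while egt8 was higher than egt17 (1.23). Flagging the list for opposite medians within the pairs favours such opposite signs. The signs thus do not decide about a difference between the library pairs. A difference between the alleles themselves was not tested.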

How the results depend on the processing

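From the labels alone no paired analysis was possible because they number only the second wild type and no mutant library. The fits with the library pair as a term rest on pairs recognised from the data and were chosen after seeing it; the other alternatives below were fixed before. With 2 libraries in each group, leaving out any leaves a lone sample that is assumed to vary like the other group, and the causes below were not tested unless stated.

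Calls of genes stayed at 0 in all 8 alternatives fixed before that kept every library, ranged from 7 to 12 when a library was left out and were 13 with the pair term. Called lists were 5, with 4 to 9 when a library was left out and 4 to 7 otherwise. Called clusters were 20: 13 with a pseudocount of 0.1, 9 with 10, 2 with a mean of at least 100 RPKM (5 clusters tested), 41 with scaling to flam and 20A, 5 with median-ratio scaling, 13 with scaling to the cluster sum, 33 with the pair term, and 2 to 46 when a library was left out. The correlation of the alleles over genes was -0.02, and 0.38 against their own wild types, -0.54 crossed and -0.14 at an FPKM of at least 5; over clusters it was 0.825, and 0.825 and 0.620. The dual-strand to uni-strand ratio kept its direction in all 12 alternatives, from -1.69 to -0.95; a mean of at least 100 RPKM left no dual-strand cluster and gave no value. A minimum fold was applied to genes and not to the camera tests of lists.

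List medians that changed sign when a library was left out ranged as follows: cluster transcription -0.27 to -0.073, processing -0.11 to 0.054, DNA damage -0.33 to 0.092, axis patterning -0.39 to 0.23, early germline -0.51 to 0.18, vitelline membrane -1.003 to 0.64, heat shock -0.13 to 0.46, immune -0.31 to 0.82, fat body -0.42 to 0.36, muscle -0.27 to 1.32, hemocytes -0.22 to 1.17 and reference genes -0.22 to 0.018. With all libraries, cluster transcription was -0.035 with the highest transcript per gene, heat shock -0.045 at an FPKM of at least 5 and -0.070 with quantile normalization, and fat body 0.15 with no filter, 0.0079 with quantile normalization and 0.013 with median-ratio scaling.

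Genes that changed sign when a library was left out ranged from -0.88 to 1.27 (copia), -0.31 to 0.75 (roo), -1.05 to 1.85 (springer), -0.56 to 0.70 (Doc), -2.14 to 0.80 (Vm26Aa), -2.47 to 0.43 (Vm34Ca), -0.88 to 1.01 (Yp3), -1.15 to 2.59 (Mhc), -1.12 to 2.12 (Act57B), -0.97 to 0.13 (nanos), -0.24 to 0.54 (Nxf3) and -0.77 to 1.55 (RpL32). Yp3 was -0.070 with quantile normalization. Further genes that kept their direction but moved by over 1.5 times when a library was left out ranged from -0.62 to -0.078 (rhi), 0.21 to 0.52 (aub), -1.81 to -0.70 (vls), -1.56 to -0.57 (moon), -0.9965 to -0.39 (exu), -0.71 to -0.35 (bcd), 0.36 to 1.38 (Xrp1), 0.49 to 1.54 (kek1), 0.077 to 1.47 (tj), 0.44 to 1.82 (vkg), 0.44 to 1.67 (Col4a1), -3.59 to -1.05 (Cp18), 0.75 to 2.15 (ZAM), 1.18 to 2.99 (I-element), 2.66 to 6.09 (Tirant), 2.204 to 4.44 (mdg3), 1.31 to 2.66 (McClintock) and 0.95 to 2.01 (CG30428). For clusters the ranges were -1.23 to 0.12 (cluster6), -0.45 to 0.49 (cluster2) and -0.13 to 0.68 (cluster29). Cluster6 was 0.0039 and cluster40, which overlaps CG40470, lncRNA:CR40053 and CG40045, was 0.22 with median-ratio scaling, cluster40 0.18 with scaling to the cluster sum and cluster2 -0.20 with scaling to flam and 20A. The other named genes and clusters kept their direction in every alternative run. Depth limits the smaller libraries: cluster114 rests on 19 reads in wild type 2.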

Other observations

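The tests of a strain difference near Boot, of genes overlapping clusters and of the 42AB difference between alleles were chosen after the result was seen; the comparison with other splits of the libraries was set before. The genes, transposons and clusters in this paragraph were chosen after their values were seen. Beyond the 2 lists, the transposons gypsy12 and McClintock were higher in both alleles, gypsy12 at 1.17 and 0.468 FPKM in wild type against 8.79 FPKM in egt17 and 23.9 FPKM in egt8, and McClintock at 2.09 FPKM in egt17 and 6.87 FPKM in egt8. As 1 list of 43, chosen after seeing the data, transposons had a median of 1.18. Of them 8 passed limma adjusted over the list alone, or 25 with the pair term. Camera gave a p of 8.68e-41 with the preset correlation and a p of 0.0594 with an estimated correlation. The 43 are those of 121 listed that passed the filter, which elements near 0 in wild type met through the mutant libraries. At the tip of 2R, where cluster97 lost most of its small RNA, the overlapping genes had more RNA in the mutants: CG9380 went from 2.32 and 1.01 FPKM to 5.95 FPKM in egt17 and 11.2 FPKM in egt8, and CG30428 from 1.07 and 1.24 FPKM to 7.69 and 3.15 FPKM. Cluster11, past the last annotated gene of 3R, fell from 6.41 and 21.65 RPKM to 0.474 and 1.63 RPKM.

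Over the 35 tested genes that overlap clusters, the median log2 difference exceeded that of the other genes by 0.179 (two-sided permutation p = 0.00643). The higher median rests on the first library pair. The permutation resampled genes, which are not independent replicates, and each within-pair comparison has a lone library on either side. In egt17 against wild type 1, 24 of these genes were higher and 11 lower, with a median of 0.30 against 0.011 for other genes (permutation p = 9.00e-05). In egt8 against wild type 2, 14 were higher and 21 lower, with a median of -0.094 against -0.11 (permutation p = 0.833); these within-pair values were added after seeing the data. Loss of host gene transcripts along with cluster small RNA predicts a lower median, which neither pair showed. The pooled difference meets neither bound set for that explanation. The test also pooled genes over all listed clusters, with Atf6 and tyf at clusters whose small RNA rose. It thus cannot decide for genes at clusters that lost small RNA, and the explanation stays open.

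At least 2-fold in both alleles, 173 genes were set apart, against 1414 for the split by library pair and 55 for the split that crosses the pairs, so the real split set apart 3.15 times as many as the crossed split. With 3 splits of the 4 libraries no share under 0.05 can be reached, and the 1414 point to a structure of the samples. For transposons the same splits gave 20, 3 and 2. A strain difference linked to the Boot locus may contribute to the 173. It was tested over the 8009 genes of known position, 160 of them set apart. Within 1 Mb of Boot 8 of 183 genes (4.37%) were set apart, against 1.94% elsewhere. That is an odds ratio of 2.31 (95% interval 0.963 to 4.76, Fisher exact p = 0.0301). CG30345 and Lime, which were called with the pair term, are among the 8. The interval holds the ratio of 3 set for that explanation, so it stays open. The interval also holds 1 although the p is under 0.05, since the exact p and the interval are formed by different rules. A background difference between Oregon-R and the mutant stocks elsewhere in the genome was not tested. For genes, transposons and clusters alike it cannot be told apart from genotype here.

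The lower 42AB small RNA of egt17 than of egt8 could come from scaling by library total or from the library pair. The log2 ratio of the RPKM of 42AB to the summed RPKM of flam and 20A, which no scaling moves, was 1.49 higher in egt8 than in egt17. That argues against scaling. The same ratio was 0.306 higher in wild type 2 than in wild type 1, which argues against the pair difference as the whole. With 1 library for each allele, a difference between the alleles stays untested.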
